A study of Arabidopsis thaliana with 32 samples.

How the data were processed

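The values come from 8 comparison tables deposited by the authors, and the sequencing reads were not used here. Per the labels, roots were dissected from seedlings preserved in RNAlater. Libraries were made from 10 ng of total RNA with a full-length cDNA kit that does not mark the strand and 8 cycles of PCR, so transcripts from opposite strands of a locus are not told apart. Per the labels, the authors used Trimmomatic 0.36, FastQC 0.11.2, STAR 2.5.1b, Picard, Cufflinks and Cuffdiff with the TAIR10 reference. The versions of the last 3 tools, the order of steps and the Cuffdiff settings are not given in the sources used here. WS tables use gene positions that differ from those of Col-0, so positions are printed for Col-0 only.

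The deposited FPKM values are the authors' Cuffdiff estimates of each group's level, made from its 4 libraries and scaled for transcript length and sequencing depth. The deposited log2 fold changes are ratios of those group values as the authors' Cuffdiff run wrote them, and were turned where needed so that flight or 8 days is the numerator. The test statistic, a score per locus in the deposited tables, is the authors' Cuffdiff statistic of that fold change. The deposited p-value and q-value of each locus are the authors' Cuffdiff results, two-sided and adjusted by them within each table for all loci tested. The tables list only loci the authors called significant, with a largest q-value of 0.0499, and 0 columns per sample. Each table was normalised separately. Levels of the same group in 2 tables differed by a median log2 ratio of -0.12 to 0.13, and levels were compared across tables in 1 test only, that of the size of 4 day flight changes, after each level had been shifted by the median ratio of its group. Levels of some hypoxia genes are also set side by side between accessions, without a shift or a test.

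The standard error of a fold change was taken as its size divided by the size of the deposited test statistic. As a check, errors of the 4 comparisons that close a loop were added as variances. The median ratio of the 2 ways round was 1.02 for 81 Col-0 loci and 1.01 for 13 WS loci. Both ways add the errors of the same 4 groups, so the ratio shows that the errors add up. It cannot show that their size is right. Cuffdiff derives its p-value by simulation, so an error interval can be wide beside a small q-value. The number of loci tested was recovered from the deposited p-value, rank and q-value of each line.

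A locus counted as called at a q-value of 0.05 or less. Loci holding several genes (13 to 125 per table) or no annotated gene (0 to 28) stayed in the counts of loci and were left out of lists and overlaps. Genes at 0 FPKM in a group stayed in counts and have no fold change. Under a limit on the size of the change they were taken as past it. Transcript length was that of the longest annotated transcript, known for 99.8% of called genes. Classes of under 800, 800 to under 2500, and 2500 nt or more were set after the length pattern had been seen.

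The 25 lists, their 474 identifiers, the comparisons, the threshold, the naming rule and the alternatives in use from the start were chosen before the data were examined. Of the identifiers, 7 were left out because the reference gives them another symbol. List sizes in the text count the members used. The naming rule took, per table, the 5 genes with the largest fold change on each side among called genes above 0 FPKM in both groups and with 5 FPKM or more in the higher group. It also took up to 4 called members per list by size of change, the 10 genes called in most flight tables, and up to 10 genes with opposite directions between tables. The value of 1 gene that the rule names is not reported here. Any gene outside the rule is said in place to have been chosen after its value was seen.

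Each list with 3 or more called members was tested by a two-sided Fisher's exact test for direction, against the other called genes of that table. A second two-sided Fisher's exact test asked whether the list's members called in any table were called in that table more often than the 4544 genes called anywhere. Each set of tests was adjusted by the Benjamini-Hochberg method over its 92 list and table pairs. Overlaps between tables that share no library were tested by a two-sided Fisher's exact test in the same 4544 genes, with the product of the called numbers over 4544 as the number expected, and 16 tests adjusted together. That background holds only called genes, because genes that were not called are not listed. The age change in flight and that on the ground share no library, nor do the accessions or the ages of a flight comparison.

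The difference of a gene's fold change between 2 such tables was divided by the root of the summed squared errors and set against a normal distribution, with 1573 differences adjusted together. This treats the deposited errors as known, although each rests on 4 replicates per group, and no exact test was possible without values per replicate. Only genes called in both tables enter it, which favours genes with large changes in each. The difference of the flight change between ages and that of the age change between flight and ground are the same quantity, opposite in sign. A gene eligible for both is therefore counted among the 1573 in each form.

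The same functions were run on simulated data. With random gene sets of the observed sizes, 2.4% to 5.4% of overlap tests passed at 0.05, and planted overlaps passed at the same unadjusted threshold in 100% of runs. Lists drawn at random passed at an unadjusted 0.05 in 0% to 6.6% of runs, and lists of 8 made wholly higher in 100%. The adjustment over 92 pairs is stricter, and the real one-sided lists of 8 in 4 day Col-0 did not pass it. Lists of 4 made wholly higher passed in 0% of runs for flight in 4 day WS and for both Col-0 age tables, so short lists could not pass there. A planted log2 difference of 2 between tables was found for 68.5% to 92.5% of genes and one of 1 for 11.8% to 55.8%, after adjustment within each comparison and with many genes changed at once. Adjustment over all 1573 differences, few of them changed, can find fewer. The simulated noise was drawn from the same errors, so these rates cannot show whether the errors are too wide. With no difference planted, 0% to 11.1% passed unadjusted, the highest in the small set of WS ages.

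Values per replicate, depth per library and transcript isoforms were not analysed here. Numbers were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9.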

Results

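Messenger RNA was measured by RNA sequencing in roots of Arabidopsis thaliana seedlings that germinated and grew on agar-type plates aboard the International Space Station. Matched seedlings grew in a ground chamber that repeated the orbital environment with a delay of 48 h. The 32 libraries form 8 groups of 4 biological replicates. The groups cross 2 natural accessions, Col-0 and WS, with 2 ages, 4 and 8 days, and with flight or ground growth. A replicate pooled 5 to 8 roots at 4 days and 2 to 3 roots at 8 days, so replicates average over plants to a different degree at each age. The 8 comparisons are flight against ground within each accession and age, and 8 against 4 days within each accession and growth condition. They address how root gene expression in orbit differed from the ground at each stage, and how far development and genetic background entered into that difference.

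Each of the authors' deposited tables lists the loci that passed their test, with 1 pooled FPKM value per group, and no value per replicate, so depth per library is unknown. Fold changes below are on the log2 scale, positive when higher in flight or at 8 days. The value after ± is the standard error implied by the deposited test statistic, with 4 replicates per group. A gene is said to rise or fall only where the authors' q-value was 0.05 or less, and a gene that is not listed is called not called, which does not show that it was unchanged. Of 4544 genes called in at least 1 table, lists of genes for 25 processes fixed beforehand were followed through all tables. The genes named by rule in each comparison were chosen on fold change with 5 FPKM or more in the higher group. Larger changes therefore exist among genes at lower levels and loci of several genes. Genes named from lists or across comparisons had no such minimum, and some stand at low levels. In the authors' deposited tables the number of called loci ran from 128 for flight in 4 day WS roots to 2235 for age in ground Col-0 roots.

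**Figure D1:**
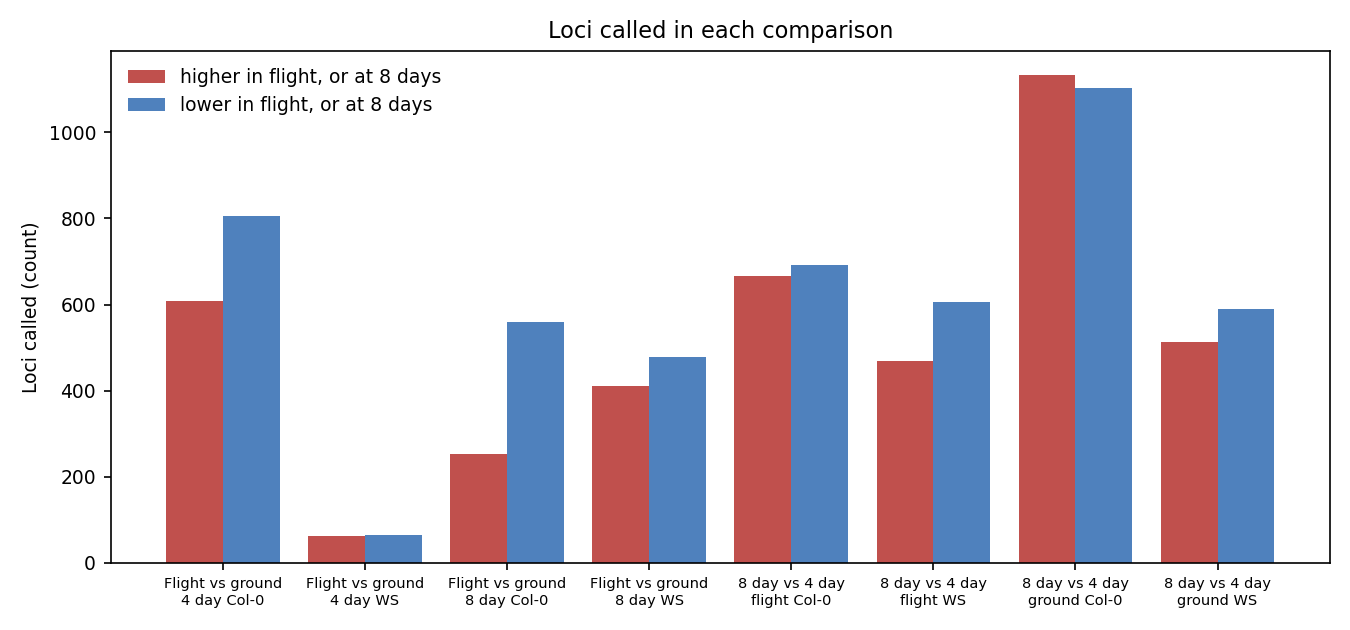
Number of loci called in each of the 8 comparisons (vertical axis, count), with loci higher in flight or at 8 days in red and lower loci in blue. The 4 day WS flight comparison stands lowest, with 63 higher and 65 lower, and the age comparison of ground Col-0 roots stands highest, with 1133 and 1102.

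In 4 day Col-0 roots, all called members of the lists for the root's barrier layers, flavonoid synthesis and peroxidases were lower in flight, while single genes such as SEN1 and bZIP1 were named among the increases. The dark-induced senescence gene SEN1 (AT4G35770, TAIR10 chromosome 4, 16944941 to 16946192) rose by 3.93 ± 0.88 in the authors' deposited table, and the transcription factor bZIP1 (AT5G49450), which acts in the response to low energy, by 2.98 ± 0.55. The peroxidase-family gene AT1G49570 rose by 3.87 ± 0.90 and the stress-tolerance gene OXS3 (AT5G56550) by 2.80 ± 0.45 in the same authors' deposited table. Decreases in the authors' deposited table were headed, by the naming rule, by BBX30 (AT4G15248) at -2.72 ± 1.32 and the early light-induced protein gene ELIP1 (AT3G22840) at -2.42 ± 0.34. They were followed in the authors' deposited table by the dirigent-like gene AT2G39430 at -2.31 ± 0.38, AT4G18422 at -2.23 ± 0.85 and the peroxidase gene PRX72 (AT5G66390), which acts in lignin formation, at -2.16 ± 0.27. The microRNA precursor MIR864 was also listed higher, at 3.73 ± 1.87 in the authors' deposited table, but FPKM is unreliable for an annotated transcript of 92 nt.

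Of the 20 genes for the Casparian strip and suberin, the barriers of the endodermis, 9 fell, 0 rose and 11 were not called. Among them were the suberin hydroxylase genes CYP86B1 (-1.55 ± 0.47) and CYP86A1 (-1.41 ± 0.52), the feruloyl transferase gene ASFT (-1.37 ± 0.48) and the Casparian strip dirigent gene ESB1 (-1.30 ± 0.33) in the authors' deposited table. Of 17 flavonoid genes, 8 fell and 0 rose, with the flavonol regulator MYB12 at -1.76 ± 0.28, CHI at -0.91 ± 0.49 and FLS1 at -0.87 ± 0.40 in the authors' deposited table. Of 19 peroxidase and NADPH oxidase genes, 8 fell and 0 rose, with PRX7 at -1.08 ± 0.65 and RCI3 at -0.92 ± 0.23 besides PRX72 in the authors' deposited table. These 3 lists held more called genes than the union of all called genes would give by a Fisher's exact test, with adjusted p = 0.0137 for barriers and 0.0053 for each of the others. The barrier call was lost with genes from 800 to under 2500 nt alone, and the other 2 could not be tested at a log2 change of 1 or more. Their direction did not pass adjustment over the 92 list and table pairs tested (Fisher's exact adjusted p = 0.0954 for each).

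Other lists in 4 day Col-0 roots had called genes but passed neither list test, and hypoxia, with under 3 called genes, was not tested. The photosynthesis list, which also serves as a set of markers for shoot or green tissue, had 6 genes lower and 0 higher of 27, including ELIP2 at -2.15 ± 0.31 in the authors' deposited table. Touch and wound genes had 4 higher and 0 lower of 19, with WRKY18 at 1.32 ± 0.47 and the calmodulin-like gene CML12, also named TCH3, at 0.87 ± 0.39 in the authors' deposited table. Xylem and secondary wall genes had 5 lower, with the laccase gene LAC17 at -1.44 ± 0.50 in the authors' deposited table. Glucosinolate genes had 6 lower and 1 higher, with the sulfotransferase gene SOT18 at -0.93 ± 0.33 and the regulator MYB51 at 1.45 ± 0.60 in the authors' deposited table. Both called hypoxia genes fell, SAD6 by -1.66 ± 0.67 and the pyruvate decarboxylase gene PDC1 by -1.53 ± 0.57 in the authors' deposited table. Nitrate genes went both ways, the authors' deposited table listing BT2 at 2.36 ± 0.78 and the nitrate reductase gene NIA1 at -1.18 ± 0.28. Called genes of the other lists, as higher and lower counts, were 2 and 5 for expansins and xyloglucan enzymes, 2 and 2 for phosphate starvation, 2 and 1 for cytokinin, 3 and 1 for detoxification, and 1 and 2 for abscisic acid and cold. In all, 608 of the 19612 loci tested rose and 806 fell. Direction moved with transcript length: 82.1% of the 123 called genes under 800 nt were higher in flight against 31.8% of the 157 of 2500 nt or more (Fisher's exact adjusted p = 7.16e-20 for short genes against the rest).

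In 4 day WS roots, far fewer loci were called than in Col-0, and photosynthesis was the only list with enough called genes to be tested. The touch-induced calmodulin-like gene TCH3 (AT2G41100) rose by 2.48 ± 0.58 and the phosphate-responsive ribonuclease gene RNS1 (AT2G02990) by 2.41 ± 0.97 in the authors' deposited table. Next in the authors' deposited table came the glutathione transferase gene GSTF3 (AT2G02930) at 2.32 ± 0.66 and the glyoxalase-family gene GLYI7 (AT1G80160) at 2.27 ± 0.89. Among decreases in the authors' deposited table were the MADS-box gene AGL42 (AT5G62165) at -2.20 ± 1.25 and the MYB gene LAF1 (AT4G25560) at -1.70 ± 0.79. The same authors' deposited table listed lower the metal transporter gene MTPA2 (AT3G58810) at -1.64 ± 0.66, the defensin-like gene AT5G33355 at -1.62 ± 0.44 and AT1G30990 at -1.53 ± 0.57. The increase of 3.66 ± 1.45 in the authors' deposited table for the microRNA precursor MIR158b (AT1G55591) belongs to a transcript of 85 nt, too short for a reliable FPKM.

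Of 27 photosynthesis genes, 4 rose in flight in 4 day WS roots and 0 fell, all of them small-subunit genes of Rubisco, the carbon-fixing enzyme. In the authors' deposited table RBCS3B rose by 1.61 ± 0.63, RBCS1B by 1.44 ± 0.60, RBCS2B by 1.21 ± 0.57 and RBCS1A by 0.98 ± 0.34; the first 3 are close paralogs that can share reads. The list held more called genes than expected (Fisher's exact adjusted p = 0.0104), a call that was lost at a log2 change of 1 or more. The list stands for green tissue as well, and 2 of the 13 seed and late embryo genes were also higher, OLEO4 at 1.33 ± 0.52 and EM6 at 1.25 ± 0.44 in the authors' deposited table. Single called members of other lists that rose in the authors' deposited table were GSTU4 at 2.14 ± 0.63, the asparagine synthetase gene ASN1 at 1.96 ± 0.69. Also higher in the authors' deposited table were the ethylene receptor gene ETR2 at 1.76 ± 0.84 and HSP90.1 at 0.89 ± 0.42, besides 2 phosphate genes. In all, 63 of the 17899 loci tested rose and 65 fell. The smallest p-value in the authors' Cuffdiff table is 5e-05, shared by 79 of these loci, so no q-value there could fall below 0.0113.

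In 8 day Col-0 roots, all called members of the lists for photosynthesis, low oxygen, cold and abscisic acid, and the clock were lower in flight. By the naming rule the decreases in the authors' deposited table included AT1G73120 at -2.68 ± 0.85, BBX30 at -2.22 ± 0.67 and the light-harvesting gene LHCB2.1 (AT2G05100) at -2.17 ± 0.48. Next in the authors' deposited table were the cold- and abscisic acid-induced gene KIN1 (AT5G15960, TAIR10 chromosome 5, 5209898 to 5210727) at -1.94 ± 0.22 and AT1G12805 at -1.84 ± 0.40. By the same rule, increases in the authors' deposited table included AT5G55620 at 2.81 ± 1.05, the cytokinin response regulator gene RR17 (AT3G56380) at 2.57 ± 1.05 and AT2G04460 at 2.06 ± 0.82. Also higher in the authors' deposited table were the short microRNA precursors MIR158b at 2.39 ± 1.34 and MIR160b at 1.82 ± 0.63.

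Of 27 photosynthesis genes, 13 fell and 0 rose in 8 day Col-0 roots, with LHCB2.2 at -2.43 ± 0.93, ELIP1 at -1.57 ± 0.23 and ELIP2 at -1.36 ± 0.22 in the authors' deposited table; both pairs of paralogs can share reads. Of 16 hypoxia genes, 8 fell and 0 rose, among them the fermentation genes PDC1 (-1.69 ± 0.30) and ADH1 (-1.39 ± 0.36) and the gene HUP26 (-0.76 ± 0.35) in the authors' deposited table. Of 19 abscisic acid, drought and cold genes, 6 fell and 0 rose, with RD29A at -0.93 ± 0.48 and KIN2 at -0.90 ± 0.16 in the authors' deposited table. Of 23 clock genes, 5 fell and 0 rose, led by PRR9 at -2.43 ± 0.90 and RVE7 at -1.43 ± 0.54 in the authors' deposited table. Jasmonate genes had 4 higher and 1 lower of 24, with the aminotransferase gene TAT3 at 1.92 ± 0.85 and the repressor gene JAZ7 at 1.63 ± 0.70 against VSP2 at -0.77 ± 0.46 in the authors' deposited table. Phosphate genes had 5 higher and 2 lower of 21, with RNS1 at 0.84 ± 0.43 and NPC4 at -0.71 ± 0.31 in the authors' deposited table. Detoxification genes had 3 higher and 1 lower of 15, with the glucosyltransferase gene UGT74E2 at 2.03 ± 0.68 and the alternative oxidase gene AOX1A at -0.44 ± 0.25 in the authors' deposited table. All 7 of these lists held more called genes than expected, with Fisher's exact adjusted p from 3.01e-05 for photosynthesis and 0.00241 for hypoxia to 0.0477 for jasmonate, detoxification and the clock. Photosynthesis kept its call under every alternative, hypoxia lost it at a log2 change of 1 or more, cold with genes from 800 to under 2500 nt alone, and the other 4 under at least 3 alternatives each. No direction test passed adjustment (smallest Fisher's exact adjusted p = 0.0954, photosynthesis).

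Of 22 root hair genes, 3 rose and 0 fell in 8 day Col-0 roots, with the cell wall protein genes PRP1 at 1.44 ± 0.45 and EXT12 at 0.90 ± 0.23 in the authors' deposited table. Casparian strip and suberin genes had 5 lower and 0 higher, including CYP86A1 at -0.68 ± 0.25, and the flavonoid regulators MYB12 at -1.15 ± 0.21 and HY5 at -0.55 ± 0.21 fell in the authors' deposited table. None of these 3 lists passed a list test. Of the remaining lists, expansins and xyloglucan enzymes had 2 genes higher and 3 lower, heat shock 2 and 1, cytokinin 2 and 2, and xylem 0 and 3. In all, 252 of 20035 loci rose and 560 fell. Of called genes by length, 17.2% of the 87 called genes under 800 nt were higher in flight against 53.0% of the 66 of 2500 nt or more (Fisher's exact adjusted p = 0.00303 for short and 0.00026 for long genes against the rest).

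In 8 day WS roots, a few hypoxia, heat-shock and root hair genes were higher in flight. The cold genes KIN1 and KIN2, which were among those lower in 8 day Col-0 roots, were lower. The desaturase gene FTM1 (AT1G43800, listed as SAD6 among the hypoxia genes) rose by 2.43 ± 0.46 and AT5G66840 by 3.06 ± 0.85 in the authors' deposited table. Also higher were AT1G12805, by 2.69 ± 0.75, AT2G14247 by 2.496 ± 1.245 and the peroxidase-family gene AT1G49570 by 2.45 ± 0.83 in the authors' deposited table. Decreases in the authors' deposited table included the receptor kinase-like gene AT4G22730 at -2.12 ± 0.75, the E6-like gene AT2G33850 at -1.76 ± 0.70, KIN1 at -1.68 ± 0.76 and KIN2 at -1.08 ± 0.23. The short transcripts MIR158b, at -3.15 ± 0.85, and the small nucleolar RNA AT3G21805, at -2.01 ± 1.21, were also listed lower in the authors' deposited table, with lengths of 85 and 91 nt.

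Of 16 hypoxia genes, 3 rose and 0 fell in 8 day WS roots, with the transcription factor gene LBD41 at 0.55 ± 0.34 and HUP26 at 0.39 ± 0.21 besides SAD6 in the authors' deposited table. Of 22 root hair genes, 3 rose, with PRP1 at 1.09 ± 0.35 and EXT12 at 0.83 ± 0.38, and of 20 heat-shock genes, 3 rose, with ROF2 at 1.40 ± 0.50 and HSP90.1 at 0.87 ± 0.38 in the authors' deposited table. Auxin genes had 3 higher and 2 lower of 21, with the lateral root gene LBD29 at -1.23 ± 0.78, and the phosphate regulator SPX1 rose by 0.86 ± 0.27 in the authors' deposited table. Iron and cytokinin genes were led in the authors' deposited table by the ubiquitin ligase gene BTS at 1.09 ± 0.40 and the response regulator gene ARR8 at 1.35 ± 0.50. Higher and lower counts were 2 and 1 for cytokinin, 2 and 1 for touch, 0 and 3 for glucosinolate and 0 and 2 for abscisic acid and cold, and no list passed either test in this comparison. In all, 410 of 17365 loci rose and 478 fell.

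Long transcripts stood apart in 8 day WS roots: 174 of the 188 called genes of 2500 nt or more were higher in flight and 14 were lower (92.6% higher, Fisher's exact adjusted p = 9.02e-52 against the rest). All 71 of 4000 nt or more were higher, while 14 genes under 800 nt were higher and 68 lower. Examples chosen after their values were seen are the chromatin genes HAC5 (1.67 ± 0.75, 5701 nt) and SYD (1.47 ± 0.70, 11033 nt) in the authors' deposited table. Others were BRM (1.11 ± 0.72, 7563 nt), PKL (1.01 ± 0.30, 4524 nt) and the DNA repair gene RAD50 (1.15 ± 0.43, 4466 nt) in the authors' deposited table. The transcripts of BTS (4495 nt) and ARF19 (4327 nt), named among iron and auxin genes, belong to this length class, and only 184 of the 410 higher loci were genes from 800 to under 2500 nt. All 11 called loci of the mitochondrial genome were also higher in flight, with a median of 1.64 and a range of 1.05 to 3.49, in the authors' deposited table.

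**Figure D2:**
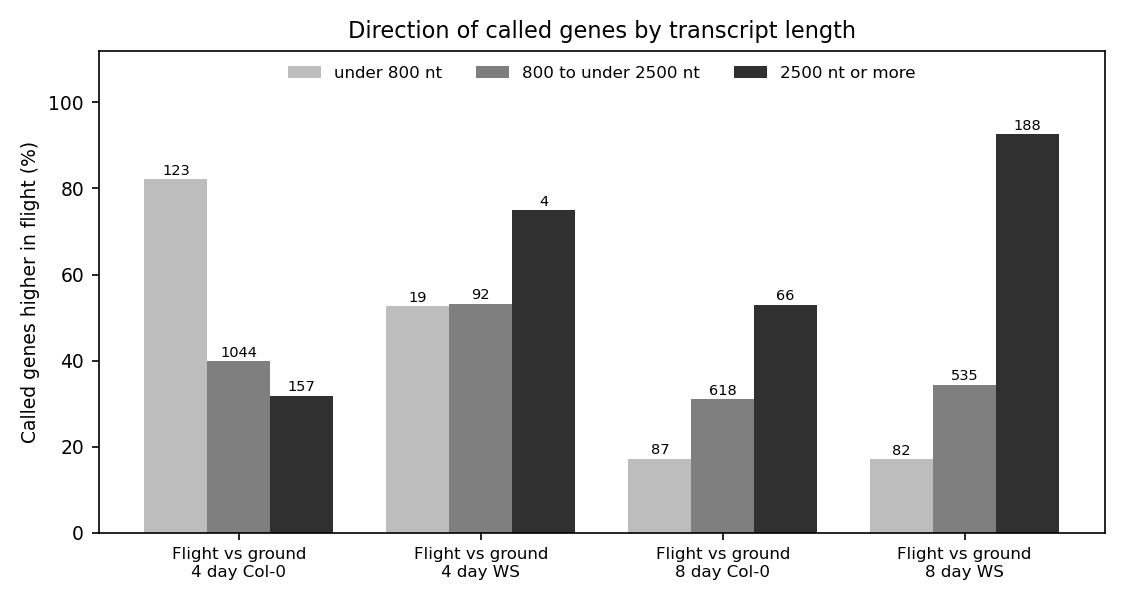
Share of called genes that were higher in flight (vertical axis, %), by transcript length class in each flight comparison, with the number of called genes above each bar. In 8 day WS roots the share reaches 92.6% for genes of 2500 nt or more and 17.1% for genes under 800 nt, while in 4 day Col-0 roots genes under 800 nt reach 82.1%.

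Between accessions, called genes mostly moved the same way in flight. At 4 days, 30 of the 33 genes called in both Col-0 and WS had the same direction and 3 the opposite, and at 8 days 123 of 134 had the same direction and 11 the opposite. Shared lower genes exceeded chance at both ages, with 19 against 8.84 expected at 4 days (Fisher's exact adjusted p = 0.000752) and 91 against 50.5 expected at 8 days (adjusted p = 5.32e-09). Shared higher genes numbered 32 against 20.02 expected at 8 days (Fisher's exact adjusted p = 0.00888) and 11 against 7.75 expected at 4 days, which did not pass (adjusted p = 0.242). The shared higher call at 8 days was lost at a q-value of 0.01 or less, and both shared lower calls at a log2 change of 1 or more.

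The direction of 2 gene groups differed between accessions, but neither difference passed adjustment once photosynthesis paralogs that can share reads were counted once. Hypoxia genes at 8 days were 0 higher and 8 lower in Col-0 against 3 higher and 0 lower in WS, and this difference passed a Fisher's exact test of direction (p = 0.00606, adjusted p = 0.0424 over 14 tests, or 0.0848 with those paralogs counted once). SAD6, LBD41 and HUP26 were called in both accessions with opposite signs. They are all of the WS genes, so the same genes stand on both sides of the test, which treats calls as independent. The test also makes no allowance for the share of all called loci higher in flight, 31.0% in Col-0 and 46.2% in WS. Photosynthesis genes at 4 days were 0 higher and 6 lower in Col-0 against 4 higher and 0 lower in WS (Fisher's exact p = 0.00476, adjusted p = 0.0424). All 4 WS genes were Rubisco small-subunit genes, so they are not independent, and with such paralogs counted once the numbers were 0 and 5 against 2 and 0 (Fisher's exact p = 0.0476, adjusted p = 0.333). The Col-0 decreases were led by ELIP1 and ELIP2, and only RBCS1A was called in both accessions, with opposite signs. Of single genes called in both accessions, 0 of 33 differed in fold change at 4 days and 3 of 134 at 8 days after adjustment over 1573 such tests, the 3 being SAD6, AT1G12805 and MIR158b. Only genes that passed in both tables could enter this test, and its errors look wide beside the authors' p-values. The small numbers therefore do not show that the other genes changed alike.

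**Figure D3:**
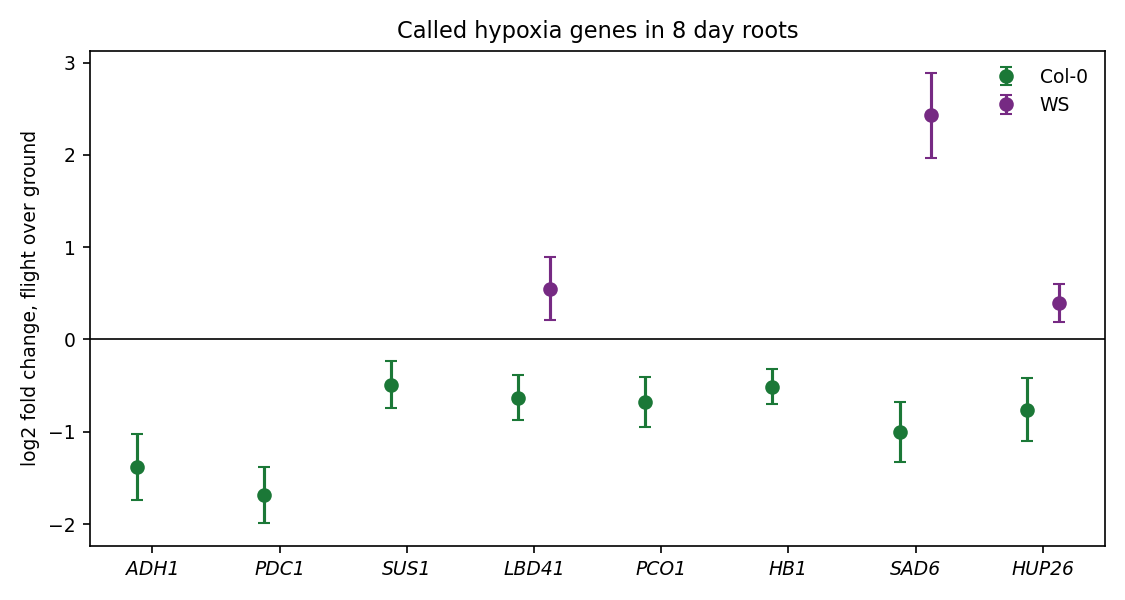
Log2 fold change, flight over ground (vertical axis), of each hypoxia gene called at 8 days, in Col-0 (green) and WS (purple), with bars of 1 standard error implied by the deposited statistic. All 8 Col-0 values lie below 0, down to -1.69 for PDC1, and all 3 WS values lie above 0, up to 2.43 for SAD6.

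A small set of genes responded to flight across ages and accessions. In the authors' deposited tables the acyltransferase-family gene AT2G39980 rose in every flight comparison, by 1.18 ± 0.72 and 1.56 ± 0.70 in 4 day Col-0 and WS and by 1.71 ± 0.77 and 1.21 ± 0.71 at 8 days. Its levels were low, from 1.57 against 0.48 FPKM in 8 day Col-0 to 6.89 against 2.34 in 4 day WS, in the authors' deposited tables. Lower in all 4 of the authors' deposited tables were the dirigent-like gene AT2G39430 (-2.31 ± 0.38, -1.02 ± 0.49, -0.41 ± 0.23 and -1.09 ± 0.31 in the same order). So were the lipid-transfer-like gene AT3G22600 (-1.22 ± 0.23 to -0.28 ± 0.16) and the vacuolar fructose transporter gene SWEET17 (-0.76 ± 0.21 to -0.32 ± 0.18) in the authors' deposited tables. AT4G29905 was also called in all 4 but rose in 4 day Col-0 (0.38 ± 0.23) and fell in the others in the authors' deposited tables. Besides these 5 genes, 81 were called in 3 flight comparisons and 429 in exactly 2. Between ages, Col-0 shared 81 higher genes against 30.3 expected and 212 lower genes against 88.2 expected (Fisher's exact adjusted p = 3.44e-18 and 5.32e-43). WS shared 22 lower genes against 5.06 expected (Fisher's exact adjusted p = 9.76e-10), while 9 higher genes against 5.13 expected did not pass (adjusted p = 0.104). The lower call in WS was lost at a log2 change of 1 or more. Among genes called at both ages, the size of the flight change was larger at 4 days for 247 of 292 Col-0 genes and 28 of 31 WS genes that kept their direction. That comparison favours whichever age had the larger error, and the median error at 4 days was the larger, 0.33 against 0.25 in Col-0.

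Age comparisons in Col-0 shared several of the genes named by rule between flight and ground, such as DIR1 and VSP2. The lipid-transfer gene DIR1 (AT5G48485), which acts in systemic defence signalling, rose from 4 to 8 days by 5.62 ± 0.77 in flight and 5.92 ± 0.69 on the ground in the authors' deposited tables. The jasmonate-induced storage protein gene VSP2 (AT5G24770) rose by 4.72 ± 1.62 and 5.97 ± 1.52 in the authors' deposited tables. AT4G33720 rose by 4.37 ± 0.61 and 4.22 ± 0.62 and AT1G52820 by 3.90 ± 0.52 and 4.28 ± 0.53 in the authors' deposited tables for flight and ground. Further increases in the authors' deposited tables were the glucosidase gene BGLU7 at 4.67 ± 0.70 in flight and the MADS-box gene AGL14 at 4.39 ± 0.59 on the ground. ECS1 (AT1G31580) fell by -4.16 ± 1.17 in flight and -4.30 ± 1.25 on the ground in the authors' deposited tables. In flight the authors' deposited table also listed lower AT1G73120 (-3.90 ± 0.88), SEN1 (-3.65 ± 0.78), AT1G09310 (-3.62 ± 0.48) and LTP (-3.56 ± 1.31). On the ground the authors' deposited table listed lower AT2G04460 (-4.86 ± 0.78), RBCS2B (-4.17 ± 1.05), the P450 gene AT3G44970 (-4.12 ± 1.26) and MLP168 (-3.58 ± 1.03).

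Of 16 hypoxia genes, 8 rose and 0 fell with age in Col-0 in each condition, with ADH1 at 1.95 ± 0.66 in flight and 2.98 ± 0.74 on the ground in the authors' deposited tables. Jasmonate genes had 8 higher and 0 lower of 24 in flight and 4 and 0 on the ground, with JAZ7 at 2.81 ± 0.98 and JAZ5 at 2.36 ± 0.68 in flight in the authors' deposited table. Casparian strip and suberin genes had 7 higher and 1 lower of 20 in flight, with CYP86A1 at 1.21 ± 0.46 and CASP5 at -1.44 ± 0.57 in the authors' deposited table, and 4 higher and 2 lower on the ground. Of 22 root hair genes, 10 fell and 0 rose on the ground, led by COBL9 at -1.11 ± 0.37 and PRP3 at -1.10 ± 0.30 in the authors' deposited table, and 3 fell in flight. Phosphate genes had 10 lower and 1 higher of 21 on the ground and 8 lower and 0 higher in flight, with the transporter gene PHT1;4 at -2.01 ± 0.29 and -1.23 ± 0.28 in the authors' deposited tables. Expansins and xyloglucan enzymes went both ways on the ground, 5 higher and 7 lower of 24, and so did detoxification genes, 2 higher and 4 lower of 15, with UGT74E2 at -2.36 ± 0.73 in the authors' deposited table. The number of called members passed in flight for jasmonate (adjusted p = 0.0053), hypoxia (0.022) and barriers (0.0394), and on the ground for expansins (0.00241), root hairs (0.0283), phosphate and detoxification (0.0477 each), all by Fisher's exact tests. Each of these 7 calls was lost under at least 1 alternative. No direction passed, the closest being root hairs on the ground (Fisher's exact adjusted p = 0.0845).

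Other Col-0 age groups passed neither list test. Root cap, cell cycle and sugar starvation had under 3 called genes and were not tested. Cytokinin genes had 6 higher and 0 lower of 19 in flight and 5 and 0 on the ground, with the response regulator gene ARR7 at 1.12 ± 0.33 and 1.25 ± 0.31 in the authors' deposited tables. Glucosinolate genes had 7 higher and 0 lower of 16 in flight, and peroxidases 0 higher and 7 lower of 19 on the ground, with MYB34 at 1.13 ± 0.40 and PRX71 at -1.34 ± 0.30 in the authors' deposited tables. The high-affinity nitrate transporter gene NRT2.1 fell by -3.17 ± 1.01 in flight and -2.72 ± 0.73 on the ground, and RBCS1B by -3.48 ± 0.80 and -3.40 ± 0.79 in the authors' deposited tables. On the ground, auxin genes had 2 higher and 6 lower, both called root cap genes fell, including RCPG at -1.76 ± 0.88, and both called cell cycle genes rose, including CYCA1;1 at 0.55 ± 0.29 in the authors' deposited table. Salicylate and defence genes had 1 higher and 2 lower in each condition, iron genes 1 and 3 in flight and 1 and 4 on the ground, and sugar starvation genes 0 and 2 in flight. Loci called higher and lower with age numbered 666 and 691 of 20007 tested in flight and 1133 and 1102 of 19905 on the ground. Called genes under 800 nt were 22.7% higher at 8 days in flight and 73.5% higher on the ground (Fisher's exact adjusted p = 6.57e-11 and 7.93e-10 against the rest), and all 3 called mitochondrial loci fell in each condition.

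In WS, single genes active in seeds, such as AT2G21820, were among the decreases named by rule from 4 to 8 days in both conditions. The seed maturation gene AT2G21820 fell by -6.94 ± 1.14 in flight and -5.56 ± 1.07 on the ground in the authors' deposited tables. AT1G03106 fell by -6.99 ± 0.68 and -5.40 ± 0.60 and the small heat-shock gene HSP17.4 (AT3G46230) by -5.81 ± 1.60 and -4.69 ± 1.51 in the authors' deposited tables. The dehydrin gene XERO1 (-6.85 ± 1.37) and AT3G05260 (-6.27 ± 1.56) fell in flight, and GLYI8 (-4.46 ± 1.35) and RBCS2B (-4.31 ± 1.25) on the ground, in the authors' deposited tables. In flight the increases named by rule in the authors' deposited table were the MADS-box genes AGL19 at 5.17 ± 4.66 and AGL42 at 4.56 ± 1.13, the germin-like gene GLP6 at 4.50 ± 1.31, AT5G44400 at 4.45 ± 1.01 and FTM1 at 4.14 ± 0.87. The AGL19 change was little larger than its implied error although it passed the authors' Cuffdiff test, and the reason was not tested. On the ground the genes named by rule in the authors' deposited table were the thioredoxin gene TH8 at 4.11 ± 0.89, AT5G44400 at 3.34 ± 0.57 and AT1G52800 at 3.296 ± 1.265, besides the short precursors MIR158b at 4.05 ± 1.35 and MIR160b at 3.37 ± 1.15.

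Of 13 seed storage and late embryo genes, 4 fell in WS on the ground (Fisher's exact adjusted p = 0.0477 for the number called) and 3 in flight, where the number called did not pass (Fisher's exact adjusted p = 0.170). The ground call was lost under 3 alternatives. The albumin genes SESA1, SESA2 and SESA3 were listed at 0 FPKM at 8 days in both of the authors' deposited tables, and OLEO4 on the ground, so no fold is given. Photosynthesis genes had 7 lower and 0 higher in flight and 5 and 0 on the ground, with RBCS3B at -4.70 ± 1.09 and -3.50 ± 1.00 in the authors' deposited tables. Hypoxia genes had 5 higher and 0 lower of 16 in each condition, with SAD6 at 4.14 ± 0.87 in flight and 1.75 ± 0.93 on the ground in the authors' deposited tables. Phosphate genes had 0 higher and 5 lower in flight and 0 and 7 on the ground, with SPX1 at -1.73 ± 0.34 on the ground in the authors' deposited table. Root hair genes had 0 higher and 5 lower on the ground, cytokinin genes 4 and 0 in flight, and sugar starvation genes 0 and 3 in flight, with ASN1 at -3.37 ± 0.86, in the authors' deposited table. Clock genes had 1 higher and 3 lower on the ground, with FKF1 at -1.72 ± 0.83 in the authors' deposited table. Apart from seed storage no WS age list passed either test. Loci called higher and lower numbered 469 and 606 of 17695 tested in flight and 514 and 590 of 18017 on the ground. Of called genes of 2500 nt or more, 30 rose and 94 fell in flight and 35 rose and 159 fell on the ground (Fisher's exact adjusted p = 2.35e-06 and 6.74e-20). Called mitochondrial loci fell, 5 of 5 in flight and 11 of 11 on the ground.

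Ageing in flight and on the ground called many genes in common. In Col-0, 344 genes rose in both against 141 expected and 275 fell in both against 146 expected (Fisher's exact adjusted p = 1.44e-82 and 2.16e-34), and 26 of 645 had opposite directions. In WS, 205 rose in both against 45.7 expected and 231 fell in both against 64.6 expected (Fisher's exact adjusted p = 4.84e-98 and 4.15e-87), and 5 of 441 had opposite directions. Between accessions, ageing shared 118 higher and 154 lower genes in flight, against 59.4 and 78.2 expected, and 182 and 164 on the ground, against 108 and 121 expected (Fisher's exact adjusted p = 5.95e-15, 3.35e-19, 1.35e-15 and 5.91e-06). By the same test of differences, which can find too few, the age change itself differed between flight and ground after adjustment for 9 of 641 Col-0 genes and 6 of 422 WS genes. PRX72 was among them in Col-0, where it rose by 0.75 ± 0.24 in flight and fell by 1.04 ± 0.22 on the ground in the authors' deposited tables.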

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

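Every explanation test below was chosen after the result had been seen, except the test of smaller changes in 4 day WS roots, which was written before its value was known.

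Called loci of the mitochondrial genome, which no list covered, were 11 of 11 higher in flight in 8 day WS roots, and transcripts of 2500 nt or more went the same way there, 174 of 188. Loss of long transcripts in the ground 8 day WS libraries would make such genes fall with age on the ground, and 82.0% of 194 did, with all 72 of the 72 flight-higher ones, a set that shares those libraries and so favours a fall; mitochondrial loci fell by a median log2 of -2.08 (11 loci) on the ground against -0.70 (5 loci) in flight in the authors' deposited tables. Long genes also fell with age in flight, 94 of 124 (75.8%), so the direction alone does not single out the ground libraries. A gain in the flight 8 day libraries would make the flight-higher long genes rise with age in flight, and only 18.18% of 22 did, although a gain set against a general fall with age is not excluded. A loss, a gain and a response of the genes themselves all stay open, since 53.0% of long genes were higher in 8 day Col-0 roots and no value per library is at hand.

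Fewer loci were called in flight in 4 day WS roots than in 4 day Col-0 roots, 128 against 1414. The number tested does not account for it, since WS had 91.3% as many loci tested. The median WS error at 4 days was 1.34 times that of Col-0, worked out from 129 WS and 202 Col-0 loci called in the other comparisons. The Col-0 changes were then given that wider error and a cutoff of 1.87, the test statistic near the edge of the WS calls. The cutoff rests on the WS calls themselves, so the count does not show what the wider error alone would leave. Together they would leave 244 Col-0 calls (95% bootstrap interval 143 to 407). The interval was drawn over loci and does not cover the spread between libraries. Wider spread may therefore account for some of the gap, and how much stays open. Smaller changes were not seen among genes called with age in flight and on the ground, 475 in WS and 689 in Col-0, whose 4 day levels came from 2 separately normalised age tables and were put on one scale by the median ratio: the median size of the flight change was 0.0930 log2 larger in WS (permutation p across loci 0.0001, the smallest that 10000 permutations can give). That was first taken to count against smaller changes, but observed size includes error, and its ratio of 1.29 does not exceed the error ratio, a rule added after the value was seen, so the question stays open.

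Hypoxia genes at 8 days in flight were all lower where called in Col-0 and all higher where called in WS (Fisher's exact p = 0.00606, adjusted p = 0.0424, or 0.0848 with photosynthesis paralogs counted once). All the WS genes were also called in Col-0, so the calls are not independent as the test assumes. The difference was led by FTM1, also named SAD6, whose fold change in Col-0 minus that in WS was -3.43 ± 0.56 in the authors' deposited tables. Transcript length did not lean that way in WS, where 38.3% of 128 genes of 1490 to 1906 nt were higher in flight. The lengths of the Col-0 genes were not checked in this way, and few genes are compared, so length is not excluded. A different oxygen supply of the accessions in flight is possible and stays open, because the same exact p of 0.00606 would follow from a difference between the ground groups, and oxygen is not given in the sources used here.

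Photosynthesis genes at 4 days also differed in direction between Col-0 and WS (Fisher's exact p = 0.00476, adjusted p = 0.0424), which did not pass with paralogs that can share reads counted once (adjusted p = 0.333). MIR158b, a transcript of 85 nt with an unreliable FPKM, differed in its flight change between 4 and 8 days in WS by 6.81 ± 1.68 and between Col-0 and WS at 8 days by 5.54 ± 1.59 in the authors' deposited tables. AT1G12805 differed between Col-0 and WS at 8 days by -4.53 ± 0.85 in the authors' deposited tables. The defensin-like gene AT5G33355 differed between 4 and 8 days in WS by -2.86 ± 0.59 in the authors' deposited tables.

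In Col-0, the flight change at 4 days minus that at 8 days was -2.23 ± 0.66 for MRN1 (AT5G42600), which encodes marneral synthase, and -1.64 ± 0.44 for UMAMIT14 (AT2G39510), a transporter gene, in the authors' deposited tables. Both fell at 4 days and rose at 8 days. The same difference was -1.90 ± 0.45 for AT2G39430, -1.80 ± 0.33 for the peroxidase gene AT5G66390, also named PRX72, and -0.94 ± 0.27 for AT3G22600, which all fell more at 4 days, in the authors' deposited tables. KIN1 fell more at 8 days, with a difference of 1.27 ± 0.39 in the authors' deposited tables. The age change of TCH3 in WS was lower in flight than on the ground by -2.32 ± 0.68 in the authors' deposited tables. Each of these gene differences passed adjustment over 1573 differences, and each gene was eligible because it was called in both tables compared.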

How the results depend on the processing

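Transcript length, mitochondrial loci, the background of loci tested, counting paralogs once and splitting of loci of several genes were alternatives chosen after the data had been seen. The others were set beforehand. Counts below are higher and lower loci.

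A q-value of 0.01 or less left, for flight, 284 and 468 in 4 day Col-0, 0 and 0 in 4 day WS, where the authors' Cuffdiff table had 63 and 65 at 0.05, 150 and 359 in 8 day Col-0, and 200 and 252 in 8 day WS. The 0 and 0 had to follow, because 79 loci of that table share the authors' smallest Cuffdiff p-value, 5e-05, so its q-values start at 0.0113. For age the threshold left 415 and 404 in flight Col-0, 257 and 325 in flight WS, 706 and 712 in ground Col-0 and 291 and 303 in ground WS.

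A log2 fold change of 1 or more in size left, for flight, 102 and 174 in 4 day Col-0, 52 and 29 in 4 day WS, 51 and 52 in 8 day Col-0 and 88 and 55 in 8 day WS. For age it left 245 and 190 in flight Col-0, 196 and 244 in flight WS, 353 and 225 in ground Col-0 and 202 and 306 in ground WS. At 2 or more in size these were 18 and 11, 13 and 1, 12 and 6, and 12 and 5 for flight, and 68 and 49, 28 and 100, 95 and 38, and 37 and 101 for age, in the same order. These counts take genes at 0 FPKM in 1 group as past each limit. Without those genes, age in flight WS had 192 and 220 at 1 or more and 100 in all at 2 or more. Age in ground WS then had 200 and 274 at 1 or more and 104 in all at 2 or more. Stricter thresholds leave fewer loci by construction. The larger side changed with fold size in all 4 flight comparisons and for age in flight Col-0; the cause was not tested.

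Genes from 800 to under 2500 nt alone left 184 higher loci for flight in 8 day WS against 410, 43 lower for flight in 4 day WS, and 365 and 330 lower for age in flight and ground WS, fewer by construction. The other 12 counts stayed within 1.5 times. Minimum levels of 1 or 5 FPKM, leaving out genes at 0 and leaving out mitochondrial loci kept all 16 counts within 1.5 times.

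Every overlap stayed above its expected number under every alternative. Of 16 overlaps, 16 kept their side of the threshold with a 5 FPKM minimum (1.34 to 4.33 times expected) and with split loci (1.38 to 4.38), and 15 with the length limit (1.34 to 4.26). At a q-value of 0.01 or less, 11 of 12 kept it (1.18 to 4.92), and the 4 that involve 4 day WS have no value for the same reason. Higher genes shared by Col-0 and WS in flight at 8 days then came to 1.18 times (Fisher's exact adjusted p = 0.489; 0.00888 at 0.05).

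With a log2 change of 1 or more, 13 of 16 kept it (1.29 to 4.87). Lower genes then shared in flight by Col-0 and WS came to 1.52 times at 4 days and 2.44 times at 8 days, and by 4 and 8 day WS to 2.71 times (Fisher's exact adjusted p = 0.323, 0.103 and 0.191). For these 3 fewer genes entered, and the cause was not tested further.

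Wider backgrounds raise every ratio by construction, to 11.3 to 37.4 with all 37899 annotated nuclear genes and 5.39 to 17.5 with the loci tested. A narrower background, of genes called in another table or in both, gave 2.098 to 7.106; it keeps every shared gene and drops genes called in only 1 of the pair, so it raises ratios by construction too. With each of the 3, 14 kept their side. The 2 others passed, which therefore adds no evidence for them: higher genes shared by Col-0 and WS in flight at 4 days, at 11.8, 5.59 and 2.23 times, and by 4 and 8 day WS, at 14.6, 6.70 and 3.37 times. The latter also passed with the length limit, at 3.03 times; the cause was not tested.

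The number of lists past the direction test was 0 under every setting by Fisher's exact test, with 9 to 26 past unadjusted and the smallest adjusted p from 0.0691 to 0.130. Lists holding more called genes than expected numbered 19, and 8 at a q-value of 0.01 or less, 5 at a log2 change of 1 or more and 10 with the length limit, where fewer genes are called by construction. They numbered 13 with a 5 FPKM minimum and 14 with split loci. Of the 19, photosynthesis in 8 day Col-0 flight passed under all 5, and peroxidases and flavonoids in 4 day Col-0 flight under all but the log2 limit, where too few genes were left to test. For flight, barriers in 4 day Col-0 and cold in 8 day Col-0 lost the call with the length limit, and photosynthesis in 4 day WS and hypoxia in 8 day Col-0 with the log2 limit. In 8 day Col-0, detoxification lost it under 4 alternatives and phosphate, jasmonate and the clock under 3 each. For age in flight Col-0, hypoxia lost it with the log2 limit, jasmonate at a q-value of 0.01 or less and barriers under 3. In ground Col-0, expansins and root hairs lost it at a q-value of 0.01 or less, and phosphate and detoxification under 4 each, and in ground WS seed storage under 3. Where lost, Fisher's exact adjusted p was 0.0506 to 1; the cause was not tested beyond the smaller number of genes. Counting photosynthesis paralogs that can share reads once left p at 0.0476 for photosynthesis between accessions at 4 days and 0.00606 for hypoxia at 8 days by Fisher's exact test, and neither passed (adjusted p = 0.333 and 0.0848; 0.0424 for both with every member). For hypoxia only the adjustment changed. Levels of a group in 2 tables kept their median ratio in all 8 groups.

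No paired analysis was possible because the tables hold 1 value per group and none per replicate. A replicate block, leaving out each replicate and other splits of samples were not run for the same reason. Adjustment over a list alone was not possible since only called loci are listed. Depth per library is unknown, so loci not called may lack reads: 17365 to 18017 loci were tested in WS against 19612 to 20035 in Col-0. At a planted log2 difference of 1, 11.8% to 55.8% of simulated gene differences were found after adjustment within each comparison, with many genes changed at once. The adjustment over all 1573 differences can find fewer, so differences of that size may have been missed.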

Other observations

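The gene families and the developmental test below were chosen after the data had been seen.

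Ribosomal protein genes formed the largest one-sided family, outside the fixed lists. In 4 day Col-0 roots 84 rose in flight and 0 fell, with AT3G06320 at 0.64 ± 0.26 and AT1G64880 at 0.64 ± 0.26 in the authors' deposited table (Fisher's exact adjusted p = 1.54e-31 over 57 families and tables). Ribosomal protein genes are short, and 57.9% of 254 other genes of the same lengths were also higher there. With age in flight, 79 fell and 2 rose in Col-0, with RPSAb at -0.51 ± 0.24, and 74 fell and 0 rose in WS, with RPS18C at -0.73 ± 0.29 in the authors' deposited tables (Fisher's exact adjusted p = 3.62e-20 and 3.29e-19). Genes of the same lengths were 40.4% and 52.2% higher with age in those tables. The flight rise and the Col-0 age fall share the 4 day flight Col-0 libraries, so a shift in those libraries alone would give both. The WS fall rests on other libraries. With age on the ground the family leaned the other way without passing, 20 higher and 6 lower in Col-0 and 6 higher and 2 lower in WS (Fisher's exact adjusted p = 0.0566 and 0.346).

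Other families past the test in 4 day Col-0 roots fell in flight. All 15 called cytochrome P450 genes fell, including CYP98A3 of lignin synthesis at -1.08 ± 0.39 and CYP705A1 at -1.32 ± 0.43 in the authors' deposited table (Fisher's exact adjusted p = 0.00388 against all other called genes). Of 90 other genes of the same lengths, only 21.1% were higher, so much of this lean is shared by genes of that length. All 13 major facilitator transporter genes fell, including AT5G46040 at -1.72 ± 0.87 in the authors' deposited table (Fisher's exact adjusted p = 0.0108), and 21.2% of 151 other genes of the same lengths were higher. Of peroxidase genes, 16 fell and 2 rose, including AT5G15180 at -1.64 ± 0.38 in the authors' deposited table (Fisher's exact adjusted p = 0.0479). With age, 15 major facilitator genes fell and 2 rose in ground Col-0, including AT3G05400 at -2.10 ± 1.22, and 9 histone genes fell and 0 rose in flight WS, including RAT5 at -0.75 ± 0.38, in the authors' deposited tables (Fisher's exact adjusted p = 0.0115 and 0.0462).

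Genes higher in flight would more often be lower with age if the cause were roots in flight behind ground roots in development. This was tested between the flight change of one accession and the age change of the other, which share no library, within genes from 800 to under 2500 nt. Of 8 table pairs, 7 had an odds ratio under 1, 6 of them past adjustment, and 0 passed above 1. With age in flight WS the ratio was 0.143 for flight in 8 day Col-0 (Fisher's exact adjusted p = 0.00147). With age in flight Col-0 it was 0.0316 for flight in 8 day WS (Fisher's exact adjusted p = 4.03e-12). With age on the ground in the other accession it was 0.0694 for 8 day Col-0 and 0.46 for 8 day WS (Fisher's exact adjusted p = 1.6e-06 and 0.0488). It was 0.806 and 1.94 in the pairs that did not pass, flight at 4 days with age on the ground (Fisher's exact adjusted p = 0.683 and 0.5). At 4 days only the pairs with age in flight passed. The accessions share growth conditions, and a flight effect alike in both would lower some ratios without a lag. These are flight at 4 days with age in flight and flight at 8 days with age on the ground, which cannot tell the 2 apart. Such an effect would raise the ratio for flight at 8 days with age in flight only if it were larger at 8 than at 4 days. Among genes called at both ages, it was larger at 4 days for 247 of 292 Col-0 genes and 28 of 31 WS genes. That count favours the age with the larger error. An effect that shrank with age would lower these ratios too, so they cannot tell it from a lag. The question of a lag stays open at both ages. An effect of length left within the range also stays open, and developmental stage was not measured by other means.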
